A study of Mus musculus with 19 samples.

How the data were processed

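Kidney RNA of 19 mice was sequenced after poly-A enrichment, with libraries made as DNA nanoballs after amplification, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which call the samples biological replicates. Each strain came in a separate table, and 0 columns of values were left without a sample.

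The deposited values are expected counts per gene, estimated counts that need not be whole (4.73% were not). Bowtie2 (aligner), RSEM (quantifier), DESeq2 and the genome build GRCm38.p6 are named in the submitters' processing notes; their versions, and how DESeq2 was used, are not given in the sources used here. Both tables list the same 16738 genes, 16622 of them of type mRNA, 50 lncRNA, 57 pseudogene and 9 other, and no gene is at 0 in every library. Coordinates come from a RefSeq table of GRCm38.p6, where 16645 of the gene IDs were found. RSEM shares a read among the genes it maps to, so genes with near-identical copies are uncertain, and BALB/c reads may map less well to the reference, which is C57BL/6.

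Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10 and robust fitting. Benjamini-Hochberg adjusted p-values under 0.05 were called. Comparisons within a strain used all libraries of that strain in a model of group means. The strain differences in effect (interactions) and the strain comparison at day 0 used all 19. The standard error of a log2 fold change was its size divided by the root of the F statistic. With totals of 18.8 to 23.2 M counts, 1 CPM is about 20 counts, and genes with few counts carry wide intervals. On simulated counts for the real genes and library sizes, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, the test was checked for each comparison, and the shares recovered are given with each result.

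In all, 33 gene lists (pathways, cell types, nephron segments and tissues beside the kidney) were fixed, and 32 could be tested; the sex-chromosome list had 0 tested members. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The latter kept 2 of 21 calls in BALB/c at day 7, 3 of 22 in BALB/c at day 21, 6 of 20 in C57BL/6 at day 7, 0 of 21 in C57BL/6 at day 21, 1 of 14 for the early and 0 of 13 for the late strain difference. The median, mean and test differed in sign for 2, 3, 4, 2, 5 and 6 lists in the same order, with 0 of these lists called. The genes of a list are not independent of each other, and list members can overlap.

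Genes were named by a rule. For infected against day 0 it took the 8 with the largest change in each direction among called genes at 5 CPM or more in the higher group whose libraries did not overlap between groups, leaving out unnamed genes and receptor segments. For the later against the earlier day and for the strains at day 0 it took 5 in each direction, for the interactions the 8 in each direction with the smallest p, and for each list up to 3 members with the smallest p, besides a fixed set of kidney and immune genes. Of this set Epo and Igkc were not analysed here. The text gives a part of the genes the rule names; 3 of them are not reported here. The groups, main tests, lists, naming rule and alternatives were fixed before the data were examined. Leaving out the 4 libraries with adrenal transcripts was chosen after seeing the data, as were the tests and genes that the text names as chosen later.

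Alternatives were size factors by the RLE method, DESeq2 1.42.0, no filter or a stricter filter on low counts (1 CPM in 3 libraries), a 2-fold minimum, the replicate number as a block, each library left out in turn, other libraries in the model, fry for lists and an estimated correlation. A result was counted as reversed where its sign changed and it passed in either setting. Overlaps of calls were tested with Fisher's exact test between strains and set against 20 simulations of unchanged groups between days. Other splits of the libraries were counted in full, or as 100 random splits for the interactions.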

Results

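Kidney transcriptomes were compared between mice infected with Trypanosoma brucei, a protozoan parasite of blood and tissue spaces, and uninfected mice of the same strain. The inbred strains were BALB/c, which the series describes as susceptible, and C57BL/6, which it describes as resistant or tolerant. Kidneys were collected before infection (day 0), early in infection (day 7) and late in infection (day 21). Each group held 3 kidneys from separate mice, except C57BL/6 day 7, which held 4, for 19 libraries in all. The RNA was poly-A enriched, and the deposited values were expected counts for 16738 genes. Day 0 was the only uninfected group, so infection and elapsed time were not separable, and the strains came in separate tables, so strain was not separable from any step applied to one table alone.

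Library totals lay between 18.8 and 23.2 M counts (M, mega). The group means were 19.5 ± 0.787 M in BALB/c day 0, 21.9 ± 0.476 in BALB/c day 7, 21.6 ± 0.596 in BALB/c day 21, 19.8 ± 0.0618 in C57BL/6 day 0, 20.7 ± 0.436 in C57BL/6 day 7 and 21.9 ± 1.17 in C57BL/6 day 21 (SD). The most abundant transcript of every library was Gpx3, a secreted glutathione peroxidase made by the proximal tubule, with 3.55% to 8.48% of the counts. In a principal component analysis the first component held 39.3% of the variance and ordered the libraries by day in each strain. The second held 21.8% and separated the strains. Throughout, levels are CPM, counts scaled to a common library size, with the SD over libraries, and log2 fold changes carry their standard error. Groups have n = 3, or n = 4 for C57BL/6 day 7, and p-values are Benjamini-Hochberg adjusted values of edgeR's quasi-likelihood test unless camera, a gene list test, is named. Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio has a 95% counting interval. Both cover counting error only.

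**Figure D1:**
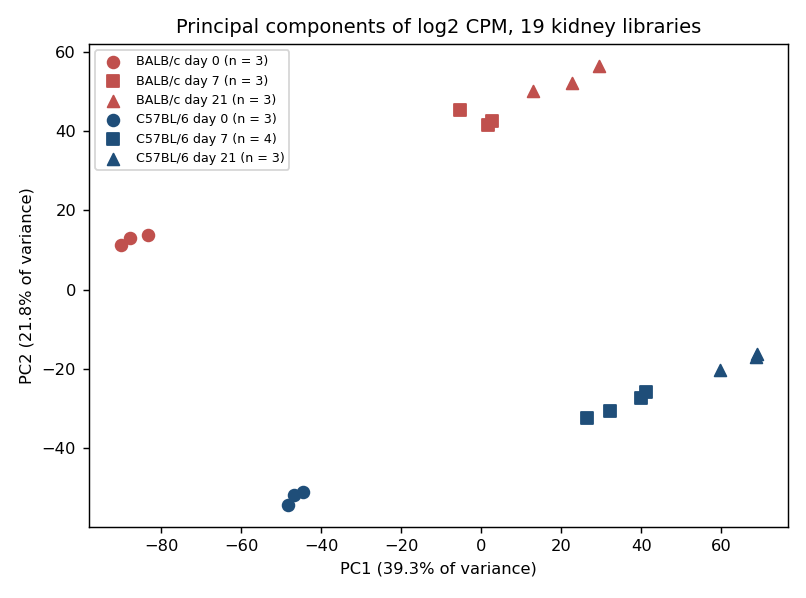
First (39.3% of variance) against second (21.8%) principal component of log2 CPM, with each point 1 library, colours for the strains and shapes for the days. On the first component the day 0 libraries lie between -90.1 and -83.2 in BALB/c and between -48.3 and -44.6 in C57BL/6, below the infected libraries of their strain.

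The early response of the BALB/c kidney was led by interferon-induced genes. Gbp10 (gene ID 626578, GRCm38.p6 chromosome 5, 105215699 to 105239533), a guanylate-binding GTPase of cell-autonomous immunity, rose 435-fold from 4.66 ± 2.31 to 2037 ± 653 CPM (log2 fold change 8.76 ± 0.49, adjusted p = 1.11e-05). Gbp6 and the GTPases Iigp1 and Tgtp1 rose 258-fold, 246-fold and 220-fold. Of 23 tested interferon-gamma-inducible GTPases and effectors, 22 rose and 1 did not pass, with 22 also when adjusted over the list alone (median log2 fold change 6.09, camera adjusted p = 2.23e-30; adjusted p = 0.107 with an estimated correlation). All 23 tested type I interferon-stimulated genes rose, 23 adjusted over the list alone, with Irf7, a transcription factor of the interferon response, up 20.1-fold from 26.4 ± 2.19 to 530 ± 82.8 CPM. Their camera adjusted p was 2.84e-25, and adjusted p = 0.107 with an estimated correlation. Reads of the Gbp, Tgtp and H2-Q families may be shared between near-identical members, so the split within each family is uncertain.

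Antigen presentation genes rose with them. All 18 tested genes of MHC class I and peptide processing rose, 18 adjusted over the list alone (median 3.89, camera adjusted p = 2.91e-29; adjusted p = 0.0963 with an estimated correlation). B2m, the class I light chain, increased 13.4-fold to 4796 ± 501 CPM and H2-K1, a class I heavy chain, 15.75-fold from 253.8 to 3994 ± 38.8 CPM. H2-Q6 had 0 counts at day 0 and 12.45 ± 2.57 CPM at day 7, at least 241.5-fold higher. All 11 class II presentation genes rose, 11 adjusted over the list alone, and this call held with an estimated correlation (median 4.10, camera adjusted p = 1.98e-17; adjusted p = 0.0344 with an estimated correlation). Cd74 (gene ID 16149, chromosome 18, 60803849 to 60812652), the invariant chain of class II molecules, rose 18.9-fold from 295.5 ± 29.9 to 5584 ± 285 CPM (adjusted p = 3.59e-10).

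Markers of leukocytes were higher at day 7. Of 23 T and NK cell markers 20 rose and 3 did not pass, with 23 adjusted over the list alone (median 3.45, camera adjusted p = 1.98e-17; adjusted p = 0.0344 with an estimated correlation). The cytotoxic granule genes Gzma and Nkg7 rose 57.95-fold and 17.4-fold. Of 22 monocyte and macrophage markers 17 rose, 19 adjusted over the list alone, among them Mpeg1, a pore-forming protein of macrophages (13.01-fold), and C1qb, a subunit of complement C1q (7.36-fold). The camera adjusted p was 1.97e-16, and adjusted p = 0.107 with an estimated correlation. Of 8 neutrophil markers 5 rose, 5 adjusted over the list alone, with a median of 3.39, or 2.66 with genes absent at day 0 at their bounds (camera adjusted p = 0.000287; adjusted p = 0.0767 with an estimated correlation). S100a8, a calcium-binding protein abundant in neutrophils, went from 0 counts to 0.793 ± 0.162 CPM, at least 15.43-fold higher. Of 14 B and plasma cell markers 0 passed, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (median 0.70, camera adjusted p = 0.257).

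Of 19 chemokines 13 rose and 6 did not pass, with 13 adjusted over the list alone (median 3.95, camera adjusted p = 2.55e-09; adjusted p = 0.107 with an estimated correlation). Cxcl10 and Cxcl9 (gene ID 17329, chromosome 5, 92321331 to 92328079), ligands of the chemokine receptor Cxcr3, rose 65.7-fold and 29.9-fold. Of 17 inflammatory cytokines and their negative regulators 11 rose and 1 fell, 15 and 1 adjusted over the list alone (camera adjusted p = 1.28e-07; adjusted p = 0.107 with an estimated correlation), and their median of 2.77 was 1.71 with bounds. Ifng went from 0 counts to 1.02 ± 0.382 CPM, at least 19.88-fold higher (adjusted p = 0.00062). Of 20 complement components 13 rose and 0 fell, 14 adjusted over the list alone (camera adjusted p = 1.27e-08; adjusted p = 0.107 with an estimated correlation). Of 25 cell cycle genes 21 rose, 23 adjusted over the list alone, with the proliferation marker Mki67 up 7.58-fold (camera adjusted p = 2.17e-10; adjusted p = 0.264 with an estimated correlation).

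Tubular transport and mitochondrial genes were lower in BALB/c at day 7. Of 25 proximal tubule transporters and receptors 10 fell, 1 rose and 14 did not pass, with 12 down and 1 up adjusted over the list alone (median -0.35, camera adjusted p = 0.000287; adjusted p = 0.365 with an estimated correlation). Slc34a1 (gene ID 20505, chromosome 13, 55399622 to 55414695), the main phosphate transporter of the proximal tubule, fell 2.04-fold from 5031 ± 438 to 2458 ± 444 CPM (log2 fold change -1.03 ± 0.15, adjusted p = 0.000346). The glucose transporter Slc5a2 fell 2.74-fold, whereas the amino acid transporter Slc6a18 rose 1.84-fold. Of 30 oxidative phosphorylation subunits 21 fell and 0 rose, with 28 down adjusted over the list alone (median -0.35, camera adjusted p = 9.58e-12; adjusted p = 0.274 with an estimated correlation). Of 23 cholesterol synthesis genes 6 fell and 1 rose, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00562; adjusted p = 0.482 with an estimated correlation). Kl (gene ID 16591, chromosome 5, 150952607 to 150993817), the FGF23 co-receptor klotho, fell 1.70-fold from 547.5 ± 20.9 to 322 ± 59.8 CPM (adjusted p = 0.000799). Of 18 circadian clock genes 6 fell and 1 rose, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00415; adjusted p = 0.216 with an estimated correlation). The largest falls by rank included Fcamr, an Fc receptor for IgA and IgM (13.6-fold), the carboxylesterase Ces1e (11.7-fold) and the orphan nuclear receptor Nr4a1 (9.98-fold).

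Some calls of other lists in BALB/c at day 7 were lost under alternatives. Of 16 glucocorticoid-responsive genes 4 fell, Sgk1 by 4.35-fold, and 2 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.482 with an estimated correlation; 0.0693 without day 7 replicate 2). Of 20 hypoxia genes 4 fell and 1 rose, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0231; adjusted p = 0.216 with an estimated correlation; 0.0949 without day 7 replicate 3). Of 25 organic ion transport and drug metabolism genes 6 fell and 3 rose, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0481; adjusted p = 0.482 with an estimated correlation). This was lost without day 0 replicate 1 (0.0741), day 0 replicate 2 (0.153) or day 7 replicate 3 (0.111), with RLE scaling (0.0617) and with the replicate block (0.0538). Of 25 loop of Henle, distal tubule and collecting duct genes 2 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.0304; adjusted p = 0.495 with an estimated correlation). It was lost without day 0 replicate 2 (0.148) or day 7 replicate 3 (0.239). Of 13 urothelium and ureter markers 4 fell, 5 adjusted over the list alone (median -0.79, camera adjusted p = 0.00132; adjusted p = 0.395 with an estimated correlation). Of 12 adipose markers 2 fell, 2 adjusted over the list alone, among them Ucp1, the uncoupling protein of brown fat, from 9.55 ± 6.93 to 0.258 CPM (camera adjusted p = 0.0466; adjusted p = 0.593 with an estimated correlation). The adipose call was lost without day 0 replicate 1 (0.0961), day 0 replicate 3 (0.416), day 7 replicate 2 (0.0693) or day 7 replicate 3 (0.0619), with RLE scaling (0.0628) and with the replicate block (0.0538).

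Of 25 tubular injury markers 8 rose and 2 fell in BALB/c at day 7, 9 and 4 adjusted over the list alone (median 0.54, camera adjusted p = 0.0921). Lcn2 (gene ID 16819, chromosome 2, 32384637 to 32387739), the iron-siderophore-binding protein NGAL, rose 5.12-fold from 4.86 to 24.9 CPM (adjusted p = 0.000628). Havcr1 (gene ID 171283, chromosome 11, 46739822 to 46779578), the injury marker KIM-1, stood at 195 ± 79.6 CPM at day 0 and 350 ± 120 at day 7 (log2 fold change 0.85 ± 0.38, adjusted p = 0.183). Adrenal transcripts stood out in BALB/c day 7 replicate 1, with 1472 CPM of the steroid 21-hydroxylase Cyp21a1, 1206 of Star and 1518 of Hsd3b1, while 0 of the 8 tested adrenal markers passed, 4 at an unadjusted p under 0.05 (camera adjusted p = 0.243, or 0.03 without day 7 replicate 2). Without that library and a day 21 library with adrenal transcripts, an alternative chosen after seeing the data, the injury list passed (camera adjusted p = 0.0467).

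In total, 1729 genes were higher and 1010 lower in BALB/c at day 7 among 14626 tested, of which 954 and 191 changed at least 2-fold. Here recoveries in simulated data were 23.9%, 71.6% and 90.9% at 1.5-fold, 2-fold and 4-fold, with 8.16% of calls false.

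The late response of the BALB/c kidney held macrophage, neutrophil and B lineage genes beside the interferon genes. Cd5l (gene ID 11801, chromosome 3, 87357881 to 87371074), a protein secreted by tissue macrophages, rose 1023-fold from 0.0658 CPM at day 0 to 75.0 ± 41 at day 21 (adjusted p = 1.78e-05), after 0.957 CPM at day 7. The monocyte chemoattractant Ccl8 rose 1365-fold to 169 ± 88 CPM (adjusted p = 3.38e-05). All 22 monocyte and macrophage markers rose, 22 adjusted over the list alone, with C1qb up 20.2-fold to 441 ± 97.6 CPM (median 4.14, camera adjusted p = 3.64e-20; adjusted p = 0.0907 with an estimated correlation). All 8 neutrophil markers rose, 8 adjusted over the list alone, and their call held with an estimated correlation (median 5.95, or 4.84 with bounds, camera adjusted p = 5.68e-10; adjusted p = 0.0180 with an estimated correlation). The granule gene Ngp went from 0 counts to 15.57 ± 1.3 CPM, at least 297-fold higher. Of 14 B and plasma cell markers 11 rose, 12 adjusted over the list alone, with the plasma cell gene Mzb1 up 45.2-fold (median 3.74, or 3.48 with bounds, camera adjusted p = 1.94e-06; adjusted p = 0.129 with an estimated correlation). All 23 T and NK cell markers rose, 23 adjusted over the list alone (camera adjusted p = 5.98e-19; adjusted p = 0.0186 with an estimated correlation).

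Interferon and antigen presentation genes stayed above day 0 levels at day 21. Of 23 type I interferon-stimulated genes 21 rose, 23 adjusted over the list alone (median 2.03, camera adjusted p = 5.24e-15; adjusted p = 0.165 with an estimated correlation). All 23 GTPases and effectors (Igtp 65.0-fold), all 18 class I genes and all 11 class II genes rose, with the same numbers adjusted over the list alone. Their camera adjusted p values were 3.22e-24, 6.31e-23 and 1.62e-16, and with an estimated correlation the adjusted p = 0.103, adjusted p = 0.103 and adjusted p = 0.0267, so that the class II call held. Cd74 rose 35.1-fold to 10330 ± 379 CPM. Of 19 chemokines 14 rose, 14 up and 1 down adjusted over the list alone (camera adjusted p = 3.79e-08; adjusted p = 0.103 with an estimated correlation). Of 17 cytokines and regulators 12 rose and 1 fell, 14 and 1 adjusted over the list alone (camera adjusted p = 1.1e-07; adjusted p = 0.103 with an estimated correlation). Of 20 complement components 14 rose and 1 fell, 15 and 2 adjusted over the list alone (camera adjusted p = 8.47e-09; adjusted p = 0.103 with an estimated correlation). Of 25 cell cycle genes 23 rose, 24 adjusted over the list alone (camera adjusted p = 1.21e-10; adjusted p = 0.222 with an estimated correlation).

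Erythroid and haem genes were higher. Of 9 erythroid genes 6 rose, 6 adjusted over the list alone (median 2.64, camera adjusted p = 0.00145; adjusted p = 0.129 with an estimated correlation), with the alpha-globin Hba-a1 up 6.34-fold from 1201 ± 306 to 7570 ± 2924 CPM and Alas2, the erythroid haem synthesis enzyme, up 7.6-fold. Of 20 iron and haem handling genes 9 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.222 with an estimated correlation), with the haem oxygenase Hmox1 up 2.84-fold. Haptoglobin (Hp, 14.5-fold, adjusted p = 0.0155) and the complement protein C3 (4.31-fold, adjusted p = 0.014) rose, calls lost without day 0 replicate 1 (0.0624 and 0.0521). The adjusted p of Hp was 0.0556 without the libraries with adrenal transcripts, 0.0518 with 2 groups only and 0.0569 with the replicate block.

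Some genes of the proximal tubule were lower. Kap (gene ID 16483, chromosome 6, 133849855 to 133853667), the androgen-regulated protein of the proximal tubule, fell 11.7-fold from 6315 ± 536 to 539 ± 151 CPM (log2 fold change -3.54 ± 0.20, adjusted p = 1.58e-07), after 6052 ± 621 CPM at day 7. The organic anion transporter family members Slc22a28, Slc22a30 and Slc22a7 fell 23.7-fold, 12.3-fold and 3.56-fold. Of 25 organic ion transport and drug metabolism genes 11 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.00376; adjusted p = 0.266 with an estimated correlation). Of 25 proximal tubule transporters and receptors 9 fell, 14 adjusted over the list alone, with megalin (Lrp2), the endocytic receptor, down 1.63-fold to 1366 ± 68.2 CPM (median -0.33, camera adjusted p = 0.000322; adjusted p = 0.307 with an estimated correlation). Of 28 fatty acid oxidation genes 10 fell, 10 adjusted over the list alone (camera adjusted p = 0.000255; adjusted p = 0.35 with an estimated correlation). Of 30 oxidative phosphorylation subunits 4 fell, 0 adjusted over the list alone (median -0.17, camera adjusted p = 0.000238; adjusted p = 0.512 with an estimated correlation).

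Of 25 loop of Henle, distal tubule and collecting duct genes 8 fell and 1 rose, 10 and 1 adjusted over the list alone, with the water channel Aqp4 down 2.74-fold and Kl down 1.86-fold (median -0.36, camera adjusted p = 0.000322; adjusted p = 0.272 with an estimated correlation). Umod (gene ID 22242, chromosome 7, 119462708 to 119479262), uromodulin of the thick ascending limb, fell 1.43-fold from 3366 ± 196 to 2338 ± 420 CPM (adjusted p = 0.0177). That call was lost without day 0 replicate 1 (0.068), day 21 replicate 1 (0.0576) or day 21 replicate 2 (0.0599). Of 15 renin-angiotensin and vitamin D genes 7 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00127; adjusted p = 0.0896 with an estimated correlation). Cyp24a1 (gene ID 13081, chromosome 2, 170482957 to 170497145), the vitamin D 24-hydroxylase, fell 7.91-fold (adjusted p = 0.0386). Its call was lost without day 0 replicate 1 (0.0564), 2 (0.0916) or 3 (0.0819), without day 21 replicate 1 (0.0999) or 2 (0.119) and without the libraries with adrenal transcripts (0.0748). Renin (Ren1) rose 1.33-fold (adjusted p = 0.0395). This call was lost without day 0 replicate 1 (0.108) or 2 (0.141), without day 21 replicate 1 (0.0947), 2 (0.108) or 3 (0.0545), without the libraries with adrenal transcripts (0.0629) and in a model of all 19 libraries (0.264). Of 18 clock genes 12 fell, 12 down and 1 up adjusted over the list alone, with the repressor Ciart down 24.7-fold (median -1.04, camera adjusted p = 2.74e-05; adjusted p = 0.103 with an estimated correlation). Of 16 glucocorticoid-responsive genes 7 fell and 1 rose, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00747; adjusted p = 0.435 with an estimated correlation).

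In the BALB/c kidney at day 21, 7 tubular injury markers rose and 2 of 25 fell, the same adjusted over the list alone (camera adjusted p = 0.39), with Lcn2 up 5.81-fold. Havcr1 stood at 105 ± 17.5 CPM (log2 fold change -0.89 ± 0.38, adjusted p = 0.137), and passed without day 0 replicate 2 (log2 fold change -1.19, adjusted p = 0.0142). The podocyte list had 2 members up and 2 down of 19, the same adjusted over the list alone (camera adjusted p = 0.561). Replicate 2 of this group held 345.5 CPM of Hsd3b1 and 61.64 of Cyp11a1, both steroid synthesis genes, while 0 of 8 adrenal markers passed, 0 also unadjusted (camera adjusted p = 0.839). Among 14626 genes 2202 were higher and 1678 lower, 1155 and 310 of them at least 2-fold. The simulated data for this comparison gave recoveries of 41.8%, 70.1% and 90.9% at 1.5-fold, 2-fold and 4-fold, with 9.68% of calls false.

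The early response of the C57BL/6 kidney was also led by interferon-induced genes. Gbp10 rose 245-fold (log2 fold change 7.94 ± 0.45, adjusted p = 1.51e-06) and Gbp2 113-fold, from 26.5 to 2998 ± 355 CPM. Of 23 interferon-gamma-inducible GTPases and effectors 22 rose, 22 adjusted over the list alone, and of 23 type I interferon-stimulated genes 23 rose, 23 adjusted over the list alone, with Irf7 up 21.4-fold. Both calls held with an estimated correlation (medians 4.88 and 3.36, camera adjusted p = 6.47e-31 and 2.95e-31; adjusted p = 0.0437 and adjusted p = 0.0351 with an estimated correlation). Of 18 class I genes 17 rose, 17 up and 1 down adjusted over the list alone (camera adjusted p = 1.95e-24; adjusted p = 0.0421 with an estimated correlation). Of 11 class II genes 9 rose, 10 adjusted over the list alone, with the peptide-loading chain H2-DMb2 up 73.5-fold and H2-Ab1 up 12.9-fold from 155 to 1995 CPM (camera adjusted p = 3.44e-15; adjusted p = 0.0421 with an estimated correlation). Chemokines (15 of 19 rose, 15 adjusted over the list alone) and cytokines with their regulators (15 of 18 rose, 16 adjusted over the list alone) also kept their calls, with camera adjusted p = 1.55e-12 and 3.15e-10, and adjusted p = 0.0351 and adjusted p = 0.0421 with an estimated correlation. Cxcl10 and Cxcl9 rose 41.8-fold and 21.9-fold, and Ifng had a ratio of 128.8 (counting interval 22.83 to 5117).

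Leukocyte markers rose in C57BL/6 at day 7. Of 23 T and NK cell markers 21 rose, 23 adjusted over the list alone, with the granule protease Gzmb up 115-fold and Nkg7 24.2-fold (camera adjusted p = 3.59e-17; adjusted p = 0.107 with an estimated correlation). Of 23 monocyte and macrophage markers 17 rose and 1, the haemoglobin scavenger receptor Cd163, fell, 18 and 1 adjusted over the list alone (median 1.82, camera adjusted p = 9.68e-11; adjusted p = 0.13 with an estimated correlation). Of 8 neutrophil markers 5 rose, 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.00419; adjusted p = 0.13 with an estimated correlation), and of 12 B and plasma cell markers 2 rose, 2 adjusted over the list alone (camera adjusted p = 0.384). Of 19 complement components 12 rose, 14 adjusted over the list alone (camera adjusted p = 2.85e-07; adjusted p = 0.13 with an estimated correlation). Of 25 cell cycle genes 23 rose, 24 adjusted over the list alone (camera adjusted p = 2.91e-11; adjusted p = 0.202 with an estimated correlation).

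Tubular injury markers rose as a list in C57BL/6 at day 7: 12 of 25 rose and 0 fell, 13 adjusted over the list alone (median 0.86, camera adjusted p = 1.14e-07; adjusted p = 0.13 with an estimated correlation). Lcn2 rose 9.52-fold from 3.84 ± 0.425 to 36.5 ± 12.1 CPM (adjusted p = 0.000219) and Havcr1 10.2-fold from 1.81 ± 0.922 to 18.4 ± 8.45 CPM (adjusted p = 0.000941). The strain difference of this effect for Havcr1 was 2.53 ± 0.69 (log2, adjusted p = 0.194). Of 25 proximal tubule transporters and receptors 16 fell and 0 rose, 16 adjusted over the list alone (median -0.66, camera adjusted p = 2.55e-08; adjusted p = 0.179 with an estimated correlation). Slc34a1 fell 1.99-fold from 6728 ± 996 to 3373 ± 856 CPM (adjusted p = 0.00036). Of 25 organic ion transport and drug metabolism genes 13 fell and 2 rose, 14 and 2 adjusted over the list alone (camera adjusted p = 5.7e-05; adjusted p = 0.274 with an estimated correlation). Of 22 endothelial genes 5 rose and 4 fell, 7 and 4 adjusted over the list alone (camera adjusted p = 0.632).

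Metabolic lists were lower in C57BL/6 at day 7. Of 23 cholesterol synthesis genes 12 fell and 2 rose, 16 and 2 adjusted over the list alone (median -0.49, camera adjusted p = 3.19e-05; adjusted p = 0.303 with an estimated correlation). Of 30 oxidative phosphorylation subunits 14 fell, 21 adjusted over the list alone (median -0.30, camera adjusted p = 7.79e-08; adjusted p = 0.361 with an estimated correlation). Of 28 fatty acid oxidation genes 9 fell, 9 adjusted over the list alone (camera adjusted p = 0.00314; adjusted p = 0.417 with an estimated correlation). Of 16 renin-angiotensin and vitamin D genes 7 fell, 8 adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.161 with an estimated correlation). Kl fell 1.85-fold from 627 ± 73 to 338 ± 41 CPM. Of 18 clock genes 2 fell, 2 adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.244 with an estimated correlation). Umod rose 1.42-fold (adjusted p = 0.0232). This was lost without day 0 replicate 1 (0.0516), 2 (0.0783) or 3 (0.0907) and without day 7 replicate 1 (0.0785) or 3 (0.0613).

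Of 12 adipose markers 1 fell in C57BL/6 at day 7, 1 adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.417 with an estimated correlation). The call was lost without day 0 replicate 1 (0.0697) or 3 (0.0715) or day 7 replicate 3 (0.0525). Ucp1 stood at 5.597, 2.839, 0.6562 and 30.76 CPM in the 4 libraries. Of 11 erythroid genes 0 passed, 1 unadjusted (camera adjusted p = 0.357, or 0.0161 without day 7 replicate 4 and 0.0109 with the replicate block), with Hba-a1 at 125.7, 882.9, 344 and 3058 CPM (adjusted p = 0.868). Of 3 tested adrenal markers 0 passed, 0 unadjusted, and of 13 urothelium markers 0, 1 unadjusted (camera adjusted p = 0.908 and 0.508). Among 14721 genes 2001 were higher and 1420 lower, 1084 and 177 of them at least 2-fold. The simulated data for this comparison gave recoveries of 44.8%, 86.6% and 93.9% at 1.5-fold, 2-fold and 4-fold, with 4.57% of calls false.

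**Figure D2:**
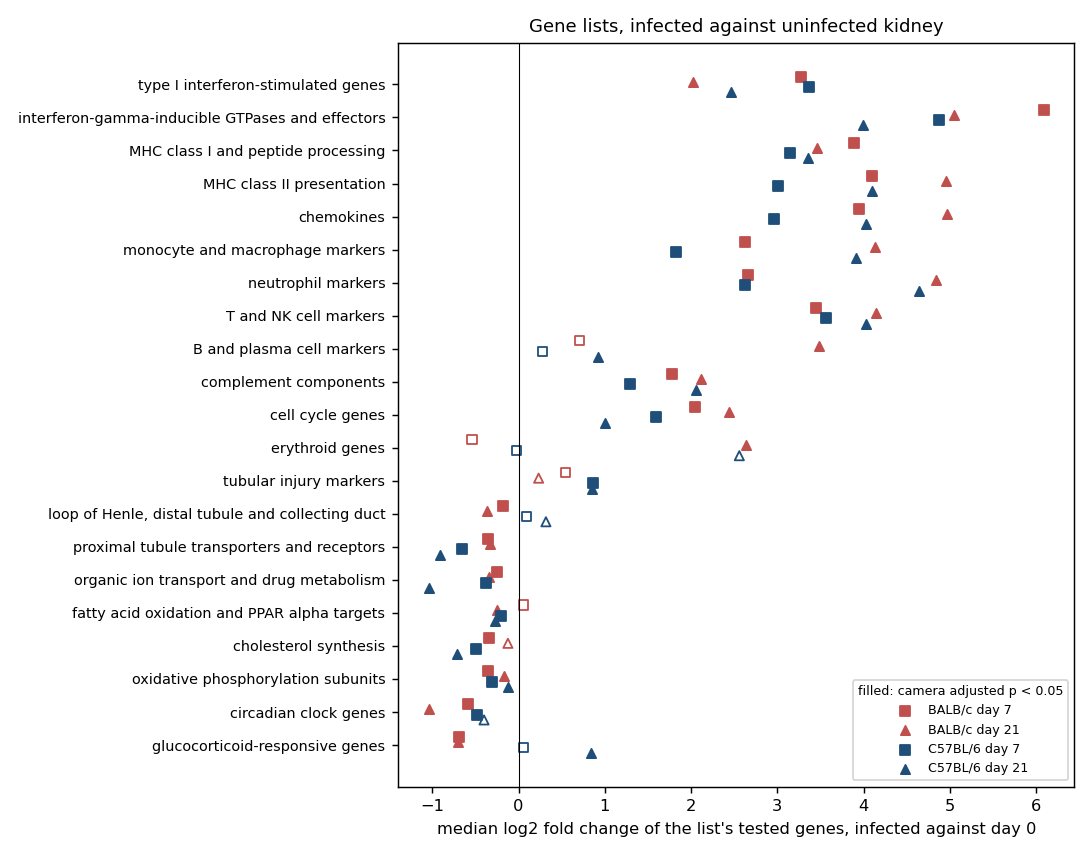
Median log2 fold change of each gene list's tested members, infected against day 0, for BALB/c (red) and C57BL/6 (blue) at day 7 (squares) and day 21 (triangles); filled points have a camera adjusted p under 0.05. Interferon, antigen presentation and leukocyte lists lie to the right, up to 6.09, and proximal tubule, organic ion and metabolic lists lie between -1.03 and 0.06, with genes absent at day 0 taken at their bounds.

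The late response of the C57BL/6 kidney combined macrophage genes with lower proximal tubule transcripts. The acute-phase gene Saa3 rose 3551-fold from 0.081 to 314 ± 158 CPM (log2 fold change 11.79 ± 1.36, or 10.82 to 13.29 over the alternatives, adjusted p = 0.000305). The macrophage genes Cd5l and Marco, a scavenger receptor, had ratios of 2691 (counting interval 744.7 to 22230) and 1449 (495.6 to 7030), reaching 93.4 ± 41.2 and 74.6 ± 8.67 CPM, and the pattern receptor Clec4e had a ratio of 705.9 (241.2 to 3425). Of 23 monocyte and macrophage markers 22 rose and 1 fell, the same adjusted over the list alone (median 3.91, camera adjusted p = 1.43e-15; adjusted p = 0.077 with an estimated correlation). Kap fell 276-fold from 11990 ± 1220 to 43.4 ± 43.9 CPM (log2 fold change -8.11 ± 0.81, or -9.373 to -7.731 over the alternatives, adjusted p = 0.0001), after 9724 ± 1070 CPM at day 7. The organic anion transporter family members Slc22a26 and Slc22a30 fell 87.4-fold and 35.0-fold, the prolactin receptor Prlr 27.3-fold and Sec14l3 26.4-fold.

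Of 25 proximal tubule transporters and receptors 21 fell and 0 rose, 22 adjusted over the list alone (median -0.91, camera adjusted p = 1.36e-08; adjusted p = 0.196 with an estimated correlation). Lrp2 fell 3.15-fold from 2682 ± 136 to 851 ± 166 CPM (adjusted p = 3.31e-07), its partner cubilin (Cubn) 2.77-fold and Slc34a1 2.42-fold to 2779 ± 251 CPM. Of 25 organic ion transport and drug metabolism genes 17 fell and 1 rose, 17 and 2 adjusted over the list alone (median -1.03, camera adjusted p = 5.77e-06; adjusted p = 0.252 with an estimated correlation). Of 23 cholesterol synthesis genes 13 fell, 13 adjusted over the list alone (camera adjusted p = 4.7e-05; adjusted p = 0.331 with an estimated correlation). Of 28 fatty acid oxidation genes 13 fell and 1 rose, 14 and 1 adjusted over the list alone (camera adjusted p = 0.00193; adjusted p = 0.377 with an estimated correlation). Of 30 oxidative phosphorylation subunits 10 fell, 9 adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.682 with an estimated correlation). The last call was lost without day 0 replicate 1 (0.0527) or 2 (0.0533), day 21 replicate 1 (0.164) or the libraries with adrenal transcripts (0.137).

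Kl fell 2.94-fold to 213 ± 24.9 CPM (adjusted p = 1.4e-07), the peptidase Mme 3.46-fold and the basement membrane collagen Col4a3 3.46-fold. Umod rose 1.77-fold from 2322 ± 115 to 4104 ± 148 CPM (adjusted p = 0.000643), while the loop of Henle, distal tubule and collecting duct list had 8 members up and 3 down of 25, the same adjusted over the list alone (camera adjusted p = 0.328). The podocyte list had 7 members up and 4 down of 19, the same adjusted over the list alone (camera adjusted p = 0.776). Cyp24a1 rose 3.40-fold to 200 ± 99.5 CPM (adjusted p = 0.0428). Its call was lost without day 0 replicate 2 (0.0769) or 3 (0.121), day 21 replicate 1 (0.0619) or 2 (0.131), without the libraries with adrenal transcripts (0.0658), with 2 groups only (0.12), with the replicate block (0.146), without a filter on low counts (0.0503) and in a model of all 19 libraries (0.0501). Of 16 glucocorticoid-responsive genes 8 rose and 0 fell, 8 adjusted over the list alone, with the metallothionein Mt2 up 3.05-fold (camera adjusted p = 0.0123; adjusted p = 0.371 with an estimated correlation; 0.0728 without day 21 replicate 1). Of 25 tubular injury markers 16 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.000109; adjusted p = 0.252 with an estimated correlation), with Lcn2 up 21.1-fold to 80.8 ± 29.9 CPM. Havcr1 stood at 1.56 ± 0.48 CPM (adjusted p = 0.79).

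Immune lists were up in C57BL/6 at day 21. All 23 type I interferon-stimulated genes and all 23 GTPases and effectors rose, 23 each adjusted over the list alone (camera adjusted p = 1.79e-15 and 7.66e-19; adjusted p = 0.077 and adjusted p = 0.0979 with an estimated correlation). Of 18 class I genes 17 rose, 18 adjusted over the list alone, and 11 of 11 class II genes rose, 11 adjusted over the list alone, with H2-Ab1 up 21.7-fold to 3358 CPM (camera adjusted p = 1.04e-16 and 2.13e-12; adjusted p = 0.077 with an estimated correlation for both). Chemokines (14 of 19 rose, 15 up and 1 down adjusted over the list alone; Ccl8 121-fold), cytokines with their regulators (16 of 18 rose, 16 adjusted over the list alone) and neutrophil markers (6 of 8 rose, 6 adjusted over the list alone) had camera adjusted p = 1.55e-08, 2.16e-09 and 0.000134. Each had adjusted p = 0.077 with an estimated correlation. Il10 and Ifng had ratios of 93.8 (counting interval 16.47 to 3740) and 244.4 (43.5 to 9689). T and NK cell markers (19 of 23 rose, 21 adjusted over the list alone) and complement components (14 of 19 rose and 1 fell, the same adjusted over the list alone) had camera adjusted p = 3.2e-12 and 5.67e-06, and adjusted p = 0.17 and adjusted p = 0.196 with an estimated correlation. Of 25 cell cycle genes 16 rose, 18 adjusted over the list alone (camera adjusted p = 0.000109; adjusted p = 0.39 with an estimated correlation), with Mki67 up 2.75-fold (adjusted p = 0.0053, or 0.111 without the libraries with adrenal transcripts). No list of this comparison kept its call with an estimated correlation.

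Of 12 B and plasma cell markers 8 rose and 2 fell in C57BL/6 at day 21, the same adjusted over the list alone (camera adjusted p = 0.0337; adjusted p = 0.284 with an estimated correlation). This was lost without day 0 replicate 1 (0.0527) or 3 (0.0878), day 21 replicate 1 (0.198), 2 (0.125) or 3 (0.0957) and the libraries with adrenal transcripts (0.106), and with the replicate block (0.0519). Of 22 endothelial genes 10 rose and 2 fell, 11 and 3 adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.3 with an estimated correlation). This was lost without day 21 replicate 1 (0.0997) or the libraries with adrenal transcripts (0.0983). Of 12 adipose markers 4 fell, 4 adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.416 with an estimated correlation). Without day 0 replicate 1 (0.0803) or 3 (0.0778) or day 21 replicate 2 (0.0797) it was lost. Of 11 androgen-responsive genes 6 fell, Kap among them, and 3 rose, 6 and 4 adjusted over the list alone (camera adjusted p = 0.224).

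Hba-a1 stood at 8671 ± 1257 CPM in C57BL/6 at day 21 against 1353 ± 547 at day 0 (adjusted p = 0.0854), and passed with 2 groups only (0.000757), in a model of all 19 libraries (0.0193) and with the replicate block (0.0303). Of 11 erythroid genes 2 rose, 1 adjusted over the list alone (median 2.56, camera adjusted p = 0.053, or 0.0272, 0.0357 and 0.043 without day 0 replicate 2, day 0 replicate 3 and day 21 replicate 3, 0.0495 without the libraries with adrenal transcripts and 0.0113 with the replicate block). In iron and haem handling 7 of 19 genes rose and 6 fell, 8 and 6 adjusted over the list alone (camera adjusted p = 0.186), with biliverdin reductase B (Blvrb) up 3.40-fold and Hmox1 3.31-fold.

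Adrenal transcripts were present in C57BL/6 day 21 replicate 3 (Cyp21a1 189.1 and Star 139 CPM) and replicate 1 (24.33 and 16.17 CPM). All 3 tested adrenal markers rose, 3 adjusted over the list alone (camera adjusted p = 0.194, or 0.0421 without day 0 replicate 3 and 0.000203 without day 21 replicate 2). Star, the steroidogenic acute regulatory protein, rose 51.4-fold (adjusted p = 0.0286). Without day 0 replicate 1 (0.0835), 2 (0.0939) or 3 (0.0814), in a model of all 19 libraries (0.0753), with 2 groups only (0.112) and with the replicate block (0.0598) it did not pass, and its log2 fold change was -0.13 without both libraries (adjusted p = 0.928). Among 14721 genes 3213 were higher and 3066 lower, 1381 and 661 of them at least 2-fold. Leaving out both libraries, which leaves 1 library at day 21 that is assumed to vary like the others, gave 4080 genes. The simulated data for this comparison gave recoveries of 46.3%, 71.6% and 92.4% at 1.5-fold, 2-fold and 4-fold, with 5.06% of calls false.

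**Figure D3:**
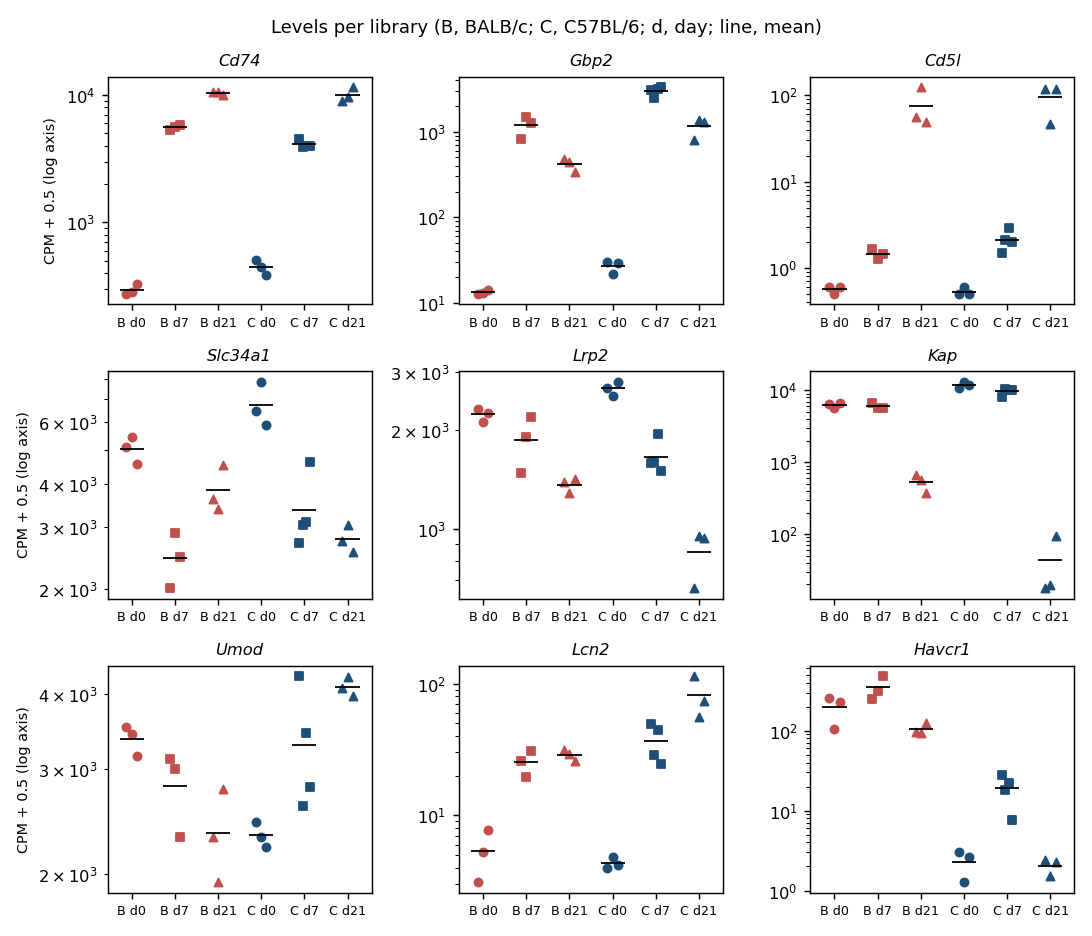
CPM + 0.5 on a log axis for 9 genes, with each point 1 library, lines at the group means and the 6 groups from left to right as BALB/c (B) and C57BL/6 (C) at days (d) 0, 7 and 21. Kap is lower at day 21 in both strains, and Umod at day 21 is lower than at day 0 in BALB/c and higher in C57BL/6.

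Day 21 was compared with day 7 in BALB/c for single genes, without list tests. Jchain, the joining chain of polymeric immunoglobulin, rose 245-fold from 1.21 to 296 ± 168 CPM (log2 fold change 7.94 ± 0.84, adjusted p = 0.00262), Cd5l 78.0-fold, Saa3 73.4-fold, the B cell coactivator Pou2af1 62.3-fold and the B cell chemoattractant Cxcl13 57.4-fold. The circadian regulators Dbp and Ciart fell 15.5-fold (adjusted p = 0.00916) and 14.3-fold (adjusted p = 0.0138) and Kap 11.2-fold. Sec14l3 fell 11.1-fold (adjusted p = 0.0317), a call lost without any one of the day 7 or day 21 libraries (adjusted p from 0.0621 to 0.101). The call of Ciart was lost without day 21 replicate 2 (0.0649), and without the libraries with adrenal transcripts the adjusted p was 0.136 for Ciart, 0.056 for Dbp and 0.146 for Sec14l3. In this comparison 934 genes were higher and 987 lower at day 21, 343 and 186 of them at least 2-fold. The total of 1921 fell to 1147 without day 7 replicate 2, 1015 without day 7 replicate 3, 1189 without day 21 replicate 2 and 1261 without day 21 replicate 3. Recoveries in simulated data were 37.3%, 71.6% and 80.3%, with 8.97% of calls false.

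Day 21 was compared with day 7 in C57BL/6 likewise. Marco rose 103-fold (log2 fold change 6.69 ± 0.29, adjusted p = 3.16e-08), Saa3 71.7-fold, Cd5l 57.2-fold and Cxcl13 36.3-fold. Kap fell 224.5-fold, Slc22a26 80.5-fold, Sec14l3 29.2-fold and Ccdc170 18.2-fold. Ucp1 was lower, with a ratio of 214.3 (counting interval 73.06 to 1041, adjusted p = 0.0323). Its call was lost without day 21 replicate 1 (0.105), 2 (0.0974) or 3 (0.099), with 2 groups only (0.0638) and without the libraries with adrenal transcripts (0.331). In this comparison 1857 genes were higher and 2112 lower at day 21, 495 and 348 of them at least 2-fold, and the total of 3969 was 1657 without the libraries with adrenal transcripts. Recoveries in simulated data were 43.3%, 76.1% and 89.4%, with 7.5% of calls false.

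The strains shared many of their calls. At day 7, 1268 genes were higher in both strains, against 234.3 for independent lists among 14402 genes tested in both, and 583 were lower in both, against 98.35 (log10 of the one-sided Fisher's exact p -892.5 and -360.9). At day 21 the numbers were 1550 against 476.6 and 1097 against 354.8 (log10 p -658.2 and -393). The strains share no libraries. Across genes, which are not independent replicates, the log2 fold changes of the strains correlated with r = 0.812 at day 7 and r = 0.790 at day 21. Between days within a strain, 1289 genes were higher and 523 lower at both days in BALB/c, against 260.3 and 115.9 for independent lists, and 1631 and 1065 in C57BL/6, against 436.7 and 295.7. Both days use the same day 0 libraries, and 20 simulations of unchanged groups against them called on average 0 genes higher at both days in BALB/c and 0.05 in C57BL/6. The correlation across genes was 0.822 in BALB/c and 0.811 in C57BL/6, against 0.496 and 0.539 in the simulations. The covariance was 0.879 and 0.728, against 0.0533 and 0.0404, a difference of 0.826 and 0.688 that estimates the shared effect. Part of the excess in calls over independent lists may come from the shared controls, since 3 control libraries cannot be split so that each part keeps 2.

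The early strain difference, C57BL/6 minus BALB/c effect, included antigen presentation genes that rose less in C57BL/6. Strain differences in read mapping were not measured. H2-DMb1, a class II peptide-loading chain, differed by -1.55 ± 0.15 (log2, adjusted p = 2.08e-05), H2-Eb1 by -1.26 ± 0.17 and Cd74 by -1.02 ± 0.16 (adjusted p = 0.007). Btnl2, a butyrophilin-like gene of the MHC region, reached 68.7 ± 12.8 CPM in BALB/c and 0.809 in C57BL/6, a difference of -5.55 ± 0.91 (adjusted p = 0.0135, or 0.157 and 0.121 without C57BL/6 day 0 replicate 2 and 3). The class I genes H2-Q8 and H2-Q7 (-2.69 ± 0.36 and -1.52 ± 0.25), which share reads with near-identical copies, the lectin receptor Clec4a2 (-2.22 ± 0.35) and the complement gene C4a (-3.50 ± 0.60), a near-copy of C4b, also had lower effects. The call of C4a (adjusted p = 0.0133) was lost without C57BL/6 day 0 replicate 2 (0.143). Of 11 class II genes 5 had a lower effect in C57BL/6, 8 lower and 1 higher adjusted over the list alone, and this was the 1 list whose call held (median -0.96, camera adjusted p = 1.55e-12; adjusted p = 0.0386 with an estimated correlation).

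In the other direction Nfkbia (gene ID 18035, chromosome 12, 55489409 to 55492647), the NF-kappa-B inhibitor, had a higher effect in C57BL/6 by 1.42 ± 0.19 (adjusted p = 0.00122). Its mean went from 112 at day 0 to 67.3 CPM at day 7 in BALB/c and from 42.6 to 67.0 in C57BL/6. Tsc22d1 (1.34 ± 0.17), the transcription factor Maff (2.09 ± 0.34) and Plekhf1 (1.17 ± 0.18) also differed. Itprip (1.19 ± 0.21) lost its call without C57BL/6 day 0 replicate 1 (0.0514) or 2 (0.0532). Dpep1 (1.10 ± 0.20), a dipeptidase of the proximal tubule, lost it without BALB/c day 0 replicate 1 (0.0659), BALB/c day 7 replicate 2 (0.0566) or C57BL/6 day 0 replicate 1 (0.0514), 2 (0.0522) or 3 (0.0594). Klf10 (1.37 ± 0.26) lost it without BALB/c day 0 replicate 1 (0.0817), BALB/c day 7 replicate 2 (0.0734) or 3 (0.0726), C57BL/6 day 0 replicate 2 (0.0768) or 3 (0.0815) or C57BL/6 day 7 replicate 1 (0.0517). Cd8a (3.05 ± 0.57), a chain of the cytotoxic T cell co-receptor, lost it without BALB/c day 0 replicate 2 (0.0929) or 3 (0.0904), BALB/c day 7 replicate 1 (0.0573) or 3 (0.0882), C57BL/6 day 0 replicate 1 (0.0567), 2 (0.0676) or 3 (0.0832), C57BL/6 day 7 replicate 2 (0.0516) or the libraries with adrenal transcripts (0.0883).

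Other lists with a lower early effect in C57BL/6 were class I (4 of 18 lower, 11 adjusted over the list alone), GTPases and effectors (1 of 23, 7 adjusted over the list alone), macrophage markers (0 of 23 with 13 unadjusted, 9 lower and 2 higher adjusted over the list alone) and complement (1 of 20, 4 adjusted over the list alone). Their camera adjusted p values were 9.05e-10, 3.13e-08, 1.66e-06 and 7.89e-05, and with an estimated correlation adjusted p = 0.42, adjusted p = 0.46, adjusted p = 0.42 and adjusted p = 0.42. Injury markers (2 of 25 higher, 4 adjusted over the list alone) and glucocorticoid-responsive genes (1 of 16 higher, 3 adjusted over the list alone) had a higher effect in C57BL/6, with camera adjusted p = 9.8e-06 and 4.94e-05, and adjusted p = 0.225 and adjusted p = 0.42 with an estimated correlation. The distal nephron list (0 of 25 with 10 unadjusted, 1 higher adjusted over the list alone) and the proximal tubule list (0 of 25 with 4 unadjusted, 1 lower adjusted over the list alone) had camera adjusted p = 0.00116 and 0.0016 with medians of 0.21 and -0.17, and adjusted p = 0.46 and adjusted p = 0.613 with an estimated correlation.

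A further 5 lists, with 0 members called over all genes or over the list alone, passed camera but not under every alternative. At an unadjusted p under 0.05 they held 2 urothelium, 4 organic ion transport, 5 fatty acid oxidation, 1 oxidative phosphorylation and 2 adrenal genes. The urothelium list (adjusted p = 0.00644; adjusted p = 0.613 with an estimated correlation) was lost without BALB/c day 7 replicate 1 (0.0637) or C57BL/6 day 0 replicate 2 (0.126). Organic ion transport (adjusted p = 0.0117; adjusted p = 0.613 with an estimated correlation) was lost without BALB/c day 0 replicate 3 (0.137) or C57BL/6 day 0 replicate 2 (0.0719). Fatty acid oxidation (adjusted p = 0.0198; adjusted p = 0.797 with an estimated correlation) was lost without BALB/c day 0 replicate 1 (0.052), BALB/c day 7 replicate 1 (0.462), C57BL/6 day 0 replicate 1 (0.077), C57BL/6 day 7 replicate 2 (0.0761) or the libraries with adrenal transcripts (0.351). Oxidative phosphorylation (adjusted p = 0.0438; adjusted p = 0.858 with an estimated correlation) was lost without BALB/c day 0 replicate 2 (0.238), BALB/c day 7 replicate 3 (0.465), C57BL/6 day 0 replicate 1 (0.0742) or 3 (0.222) or C57BL/6 day 7 replicate 4 (0.799), with RLE scaling (0.0607) and with the replicate block (0.813). The adrenal list (adjusted p = 0.0438; adjusted p = 0.797 with an estimated correlation) was lost without BALB/c day 0 replicate 1 (0.117) or 2 (0.0896), C57BL/6 day 0 replicate 1 (0.115), 2 (0.0643) or 3 (0.0807) or C57BL/6 day 7 replicate 1 (0.0673), 3 (0.0517) or 4 (0.0543), with RLE scaling (0.0607) and with the replicate block (0.0569), and it changed sign without BALB/c day 7 replicate 1 (0.935).

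In total the early effect differed between strains for 51 of 15081 genes, 22 higher and 29 lower in C57BL/6. DESeq2 called 180, and 1439 had an unadjusted p under 0.05. Without single libraries the total was 17 and 29 (BALB/c day 0 replicates 1 and 3), 25 and 22 (BALB/c day 7 replicates 2 and 3), 33, 16 and 28 (C57BL/6 day 0 replicates 1, 2 and 3) and 26, 23 and 29 (C57BL/6 day 7 replicates 1, 2 and 3), and without all libraries with adrenal transcripts it was 98. Recoveries in simulated data were 11.9%, 56.7% and 78.8% at 1.5-fold, 2-fold and 4-fold, with 2.86% of calls false.

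The strain difference in the late response went in opposite directions for the proximal tubule and distal nephron lists. Neither call held with an estimated correlation. Of 25 proximal tubule transporters and receptors 11 had a lower effect in C57BL/6, 15 adjusted over the list alone (median -0.62, camera adjusted p = 3.28e-06; adjusted p = 0.319 with an estimated correlation). Of 25 distal nephron genes 7 had a higher and 1 a lower effect, 12 and 1 adjusted over the list alone (median 0.70, camera adjusted p = 1.87e-05; adjusted p = 0.319 with an estimated correlation). Umod and Cyp24a1, chosen after their values were seen, went down in BALB/c and up in C57BL/6, with differences of 1.37 ± 0.23 (adjusted p = 0.00109) and 4.77 ± 0.99 (adjusted p = 0.00946), and Kap, chosen likewise, differed by -4.54 ± 0.68 (adjusted p = 0.00141). Of 16 glucocorticoid-responsive genes 8 had a higher effect in C57BL/6, 12 adjusted over the list alone (median 1.57, camera adjusted p = 3.23e-08; adjusted p = 0.319 with an estimated correlation). Nfkbia differed by 2.11 ± 0.19 (adjusted p = 8.89e-06), at 68.6 CPM in BALB/c and 111 in C57BL/6 at day 21. Among the genes with the smallest p, the effect was also higher in C57BL/6 for Maff (2.88 ± 0.35), the transcription factors Klf10 (2.27 ± 0.27) and Klf13 (1.19 ± 0.14), the retinoid transporter Abca4 (2.05 ± 0.21), Itprip (1.96 ± 0.22), the epithelial adhesion molecule Epcam (1.28 ± 0.15) and Sh2d3c (1.23 ± 0.14). It was lower for H2-DMb1 (-1.54 ± 0.15), Unkl (-1.66 ± 0.17), Col4a3 (-1.28 ± 0.14), the acyltransferase Acnat1 (-1.64 ± 0.20), the mitochondrial serine transporter Sfxn1 (-0.92 ± 0.12) and Parp11 (-1.74 ± 0.23).

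B and plasma cell markers had a lower late effect in C57BL/6 for 6 of 16 genes, 6 adjusted over the list alone (median -3.01, camera adjusted p = 6.87e-05; adjusted p = 0.319 with an estimated correlation). Organic ion transport (9 lower and 1 higher of 25, 11 and 1 adjusted over the list alone), class II (5 lower and 1 higher of 11, 7 and 1 adjusted over the list alone) and injury markers (5 higher of 25, 7 adjusted over the list alone) had camera adjusted p = 6.87e-05, 0.000124 and 7.01e-05. Each had adjusted p = 0.319 with an estimated correlation. Cell cycle genes (2 lower of 25, 11 adjusted over the list alone), cholesterol synthesis (6 lower of 23, 9 adjusted over the list alone), GTPases (6 lower of 23, 7 adjusted over the list alone) and endothelial genes (4 higher of 22, 5 up and 1 down adjusted over the list alone) had camera adjusted p = 6.87e-05, 0.000185, 0.00025 and 0.00389. With an estimated correlation they had adjusted p = 0.614, adjusted p = 0.439, adjusted p = 0.669 and adjusted p = 0.321, and the endothelial call was lost without the libraries with adrenal transcripts (0.148).

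Class I genes (3 lower of 18, 4 adjusted over the list alone; camera adjusted p = 0.0426; adjusted p = 0.807 with an estimated correlation) lost their late call without BALB/c day 0 replicate 1 (0.115) or 2 (0.111), C57BL/6 day 0 replicate 1 (0.143), BALB/c day 21 replicate 1 (0.1) or 2 (0.0538), C57BL/6 day 21 replicate 1 (0.271) or the libraries with adrenal transcripts (0.263), and with the replicate block (0.0595). Clock genes (3 higher of 18, 6 up and 1 down adjusted over the list alone; camera adjusted p = 0.0496; adjusted p = 0.411 with an estimated correlation) lost theirs without BALB/c day 0 replicate 1 (0.115), C57BL/6 day 0 replicate 1 (0.0794), BALB/c day 21 replicate 1 (0.066) or 2 (0.0511) or C57BL/6 day 21 replicate 2 (0.206). In total 1404 of 15081 genes differed, 610 higher and 794 lower in C57BL/6, or 849 without the libraries with adrenal transcripts. At day 21, 58 genes were called higher in BALB/c and lower in C57BL/6 and 65 the reverse, and each of these 123 was also called in the test of the difference. Recoveries in simulated data were 8.96%, 40.3% and 83.3%, with 4.17% of calls false.

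Before infection the strains differed in globin genes, among others. In C57BL/6 relative to BALB/c at day 0, the beta-globin Hbb-bs had a ratio of 33350 (counting interval 5985 to 1317000) at 564 ± 254 CPM and Hbb-bt was at least 2005-fold higher, while Hbb-b1 was 1895-fold lower and Hbb-b2 lower with a ratio of 2143 (592.8 to 17700). Eno1b was lower with a ratio of 10190 (3485 to 49400) and Hmga1b 111-fold lower, while Rpl29 was 139.5-fold higher. Near-identical copies blur these values, and the nearly all-or-none beta-globins may not reflect expression. Akr1c21, an aldo-keto reductase, and Methig1 were 706-fold and 196-fold higher in C57BL/6. Havcr1 was 108-fold lower in C57BL/6 (log2 difference -6.76 ± 0.59, adjusted p = 2.84e-06), at 1.81 ± 0.922 against 195 ± 79.6 CPM. Among 15081 genes 1184 were higher and 921 lower in C57BL/6, 486 and 291 of them at least 2-fold. Recoveries in simulated data were 41.8%, 68.7% and 81.8%, with 2.82% of calls false.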

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

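The tests of proximal tubule share, of the S3 segment against the pattern, of time of day (in both patterns), of an immediate-early response and of variants against the reference were chosen only after the result was seen.

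A test of the difference between strains picked out the results of this paragraph, as C57BL/6 minus BALB/c log2 effects. At day 7, 51 genes passed, with the named ones Btnl2 (-5.55), C4a (-3.50), H2-Q8 (-2.69), Clec4a2 (-2.22), H2-DMb1 (-1.55), H2-Q7 (-1.52), H2-Eb1 (-1.26), Cd74 (-1.02), H2-Ab1 (-0.84), H2-Aa (-0.79), Plekhf1 (1.17), Itprip (1.19), Dpep1 (1.10), Tsc22d1 (1.34), Klf10 (1.37), Nfkbia (1.42), Maff (2.09) and Cd8a (3.05). H2-Q6 had a fitted difference of -15.98, which depends on the prior count since it had 0 counts in BALB/c at day 0. The list medians were -6.40 (adrenal), -0.96 (class II), -0.88 (macrophage), -0.80 (GTPases), -0.58 (class I), -0.47 (complement), -0.22 (organic ion), -0.21 (fatty acid oxidation), -0.17 (proximal tubule), 0.10 (oxidative phosphorylation), 0.21 (distal nephron), 0.61 (injury), 0.87 (urothelium) and 0.90 (glucocorticoid).

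At day 21, 1404 genes passed. Lower effects in C57BL/6 were found for Kap (-4.54), Ccl8 (-3.47), Cd22 (-2.69), Slc22a7 (-2.25), Parp11 (-1.74), Unkl (-1.66), Acnat1 (-1.64), Sall2 (-1.57), Prlr (-1.57), H2-DMb1 (-1.54), Igtp (-1.35), Col4a3 (-1.28), AI464131 (-1.07), Lrp2 (-0.93), Mme (-0.93), Slc22a6 (-0.93), Sfxn1 (-0.92), Slc34a1 (-0.87), Cubn (-0.82), Kl (-0.64) and Cd74 (-0.63). Higher effects were found for Irf7 (1.00), Klf13 (1.19), Sh2d3c (1.23), Blvrb (1.246), Epcam (1.28), Umod (1.37), Lcn2 (1.88), Itprip (1.96), Abca4 (2.05), Nfkbia (2.11), Mt2 (2.15), Klf10 (2.27), Maff (2.88), Cyp24a1 (4.77) and Ciart (5.78). The list medians were -3.01 (B and plasma cell), -1.44 (cell cycle), -0.67 (GTPases), -0.63 (class II), -0.62 (proximal tubule), -0.59 (cholesterol), -0.52 (organic ion), -0.37 (class I), 0.29 (endothelial), 0.64 (clock), 0.68 (injury), 0.70 (distal nephron) and 1.57 (glucocorticoid).

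Of 62 values tested in the 4 libraries of C57BL/6 day 7, Ucp1 in replicate 4 stood apart, its gap to the others taking 0.836 of the range, above Dixon's critical value; chance alone picks out about 1 in 20 such groups.

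Kap, Prlr, Slc22a26, Slc22a28, Slc22a30, Sec14l3 and Ccdc170 were all lower at day 21, with medians of -3.48 in BALB/c and -4.77 in C57BL/6. A smaller proximal tubule share and pieces without S3 are argued against as sole causes. The tubule list lay above these genes by 3.15 ± 0.36 in BALB/c and 3.86 ± 0.66 in C57BL/6. Other S3 genes (medians -0.31 ± 0.14 and -0.77 ± 0.24) lay above by 3.16 ± 0.38 and 4.00 ± 0.69. Kap and the rest were picked for large falls, so a part stays open. Another time of day at day 21 also stays open, with 5 of 7 clock phase genes called in BALB/c and 1 in C57BL/6. A response to infection in genes under hormonal control stays open as the biological alternative: of 11 androgen-responsive genes 2 fell and 1 rose in BALB/c and 6 and 3 in C57BL/6 (camera adjusted p = 0.105 and 0.224).

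Of the 1404 genes of the late strain difference 37.7%, less than an even split, differed more between strains at day 0 than at day 21. Of them 561 were also called at day 0, against 196 for independent lists, but noise in the shared day 0 libraries alone raises this number. How much of the late difference lies at day 0 is therefore not shown, and the tests below concern the strains at day 0. Another time of day for the BALB/c day 0 mice stays open, with 1 of 7 clock phase genes called. An immediate-early response at harvest stays open, with 2 of 13 such genes called higher in BALB/c and 0 in C57BL/6 (median -0.15 ± 0.29). A glucocorticoid response in the BALB/c day 0 mice is a candidate explanation, since the glucocorticoid list had a median of -1.05 ± 0.26, with 9 of 16 genes higher in BALB/c and 0 in C57BL/6 (camera adjusted p = 2.07e-07; adjusted p = 0.365 with an estimated correlation). This call does not hold with an estimated correlation, and the day 0 difference is itself a term of the late strain difference in which the list was found. A lasting strain difference stays open as the biological alternative, untested.

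Havcr1 differed between the strains before infection. Reads lost to variants are argued against, because the lower strain, by -6.76 ± 0.59, is the one the reference comes from. Reads assigned to a related gene are argued against, since the largest gain in C57BL/6 was 0.191% of the Havcr1 difference. Tubular injury in uninfected BALB/c stays open: the other injury markers went both ways, with 4 of 24 higher in each strain, so a bound on their median (-0.15 ± 0.32) does not decide it. A strain difference in the regulation of Havcr1 was not tested.

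Other splits of the libraries bear on the counts of called genes. C57BL/6 day 7 against day 0 (3421 genes, highest other 1005) and day 21 against day 7 (3969, highest other 947) had 35 splits each. Only the real split was as large, but without adjustment over comparisons chance stays open. With 10 splits, BALB/c day 7 (2739) and day 21 (3880) against day 0, BALB/c day 21 against day 7 (1921), C57BL/6 day 21 against day 0 (6279) and the strains at day 0 (2105) had a highest other of 0, and the splits are too few for a share under 0.05. For the interactions 6 of 100 splits gave as many as the 51 genes at day 7 (highest other 4225) and 7 of 100 as many as the 1404 at day 21 (highest other 4586), so chance cannot be excluded by this count. The splits with the highest counts exchange most or all day labels within 1 strain, which points to the effect of infection itself.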

How the results depend on the processing

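The libraries with adrenal transcripts were left out only after the results were seen. Of 206 results for named genes 200 were called, and 179 of these kept direction and call under every alternative run; of the 6 not called, 2 passed under an alternative. RLE scaling, both filters and other libraries in the model kept all counts within 1.5 times. Depth limits genes with few counts, whose folds are bounds or wide intervals. Where a result changed, the cause was not tested, except that a fold minimum lowers counts by construction.

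With a minimum of 2-fold the counts became 1145 (BALB/c day 7), 1465 (BALB/c day 21), 1261 (C57BL/6 day 7), 2042 (C57BL/6 day 21), 529 and 843 (day 21 against day 7, BALB/c and C57BL/6), 511 (late strain difference) and 777 (strains at day 0). Shared calls became 790 higher and 73 lower between strains at day 7, 915 and 159 at day 21, and between days 807 and 87 in BALB/c and 909 and 110 in C57BL/6. DESeq2 called 180 genes for the early strain difference.

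Without the libraries with adrenal transcripts C57BL/6 gave 4080 genes at day 21 and 1657 for day 21 against day 7, and the strain differences 98 and 849. Star turned to -0.13 in C57BL/6 at day 21, and in the list tests the sign turned for extracellular matrix in C57BL/6 at day 21 (adjusted p = 0.0446) and for adrenal markers in the early strain difference (adjusted p = 0.821). With an estimated correlation the called lists numbered 2 and 3 in BALB/c and 6 and 0 in C57BL/6 (days 7 and 21), and 1 and 0 for the strain differences. By fry 1 list was called for the early strain difference.

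Leaving out each library in turn gave 1838 to 2647 genes for BALB/c day 7, 2779 to 3599 for BALB/c day 21, 2534 to 3561 for C57BL/6 day 7, 5268 to 5818 for C57BL/6 day 21, 1015 to 1620 and 3086 to 4191 for day 21 against day 7 in BALB/c and C57BL/6, 16 to 62 and 941 to 1377 for the strain differences and 1486 to 1680 for the strains at day 0. The result for adrenal gland markers, strain difference in the day 7 effect, ranged over adjusted p = 0.000381 to 0.935.

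Same-numbered libraries did not deviate together (correlations -0.232 to 0.0856 in BALB/c and -0.143 to 0.117 in C57BL/6), and 5 of 19 libraries correlated best with their own number, so the numbers do not pair the mice. With the number as a replicate block 2348, 3421, 3634 and 6538 genes were called in BALB/c day 7 and 21 and C57BL/6 day 7 and 21, 1438 and 4259 for day 21 against day 7, 43 and 1405 for the strain differences and 2042 for the strains at day 0. The block list counts were 19, 22, 21, 21, 14 and 12, in the order of the infected comparisons and the strain differences.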

Other observations

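The libraries with adrenal transcripts were left out only after the results were seen. Lists not described above showed few or mixed changes. Of 27 extracellular matrix and fibrosis genes 4 rose and 3 fell in BALB/c at day 7 (6 and 4 adjusted over the list alone), 4 and 3 at day 21 (4 and 3), 5 and 2 in C57BL/6 at day 7 (6 and 3) and 6 and 3 at day 21 (6 and 2). Their camera adjusted p values were 0.668, 0.0586, 0.788 and 0.809. In BALB/c at day 21 the list passed without day 0 replicate 3 (0.00249) or day 21 replicate 1 (0.0412) or 3 (0.0295), and in C57BL/6 at day 21 it changed sign without the libraries with adrenal transcripts (0.0446). For the strain differences some further lists passed only under alternatives, among them T and NK cell markers, cholesterol synthesis and chemokines at day 7 and neutrophil markers and complement at day 21. Of 19 podocyte genes 0 were called in BALB/c at day 7 by edgeR, 1 at an unadjusted p under 0.05 (camera adjusted p = 0.372).

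Genes called in opposite directions in the strains were fewer than independent lists give. At day 21 there were 123 against 828 expected, a ratio of 0.149, which argues against independent calls in the strains.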
